A study of Mus musculus with 10 samples.

How the data were processed

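RNA from visual cortex of wild-type C57Bl6 mice was measured on 10 one-colour Affymetrix oligonucleotide arrays of 12488 probe sets, one array per sample. Per the labels, one eye was removed at postnatal day 14 and the cortex was taken 4 days later, at postnatal day 18. The 5 deprived samples came from the hemisphere contralateral to the removed eye and the 5 non-deprived samples from the ipsilateral hemisphere. Groups and replicate numbers were read from the sample titles. The labels speak of pooled samples and of 4 mice, and do not say how the animals were divided over the 10 samples or whether same-numbered samples share animals. The p-values therefore measure the spread between these samples, part of which may be technical. Per the labels' protocols, total RNA was extracted with Trizol and about 10 µg was used to make biotin-labelled cRNA.

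The deposited values are MAS5 signal intensities, 1 per probe set and array, on a linear scale; MAS5, Affymetrix's summary of perfect-match and mismatch probes, is named in the submitters' processing notes. Its version and the scaling target are not given in the sources used here. In the deposited intensities, the mean of each array after leaving out the lowest and highest 2% of probe sets was 500 after rounding on all 10 arrays, so the arrays had been scaled to a common level before deposit. A global scaling of this kind removes any difference in total RNA per cell, so that all changes are relative to the array's average. The intensities ranged from 0 to 36786, none was missing or below 0, and no array repeated another. No detection calls were used here, so low intensities were not set against background. Array data carry no read depth, and the number of arrays limits the precision.

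The 66 control probe sets were left out of the tests, which left 12422. A platform annotation table, with symbols updated through Entrez IDs, gave 10833 of these probe sets 1 gene symbol, 396 several and 1193 none; 10817 of the single symbols were matched through their Entrez ID. Only probe sets with 1 symbol are named. No genome build belongs to these values and no coordinates are given. Suffixes mark probe sets of lower specificity or with fewer probes: f for a sequence family, g for a group of similar sequences, r for relaxed design rules, i for an incomplete set and s for a sequence shared between transcripts.

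Intensities were converted to log2(value + 16), where 16 is the 10th percentile of all values in the table. Fold changes on this scale understate the change of dim probe sets. Array medians differed by at most 1.10-fold, so no further normalization was applied. Probe sets whose mean log2 value over all 10 arrays lay below the 40th percentile were left out, and 7453 were tested. The comparison was deprived minus non-deprived in limma 3.58.1 (R 4.3.3; lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment at 0.05 and no covariate. An adjusted p in the text is from this limma fit unless another test is named.

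A panel of 15 activity-regulated genes and 18 gene lists were fixed before the data were examined, together with the tests and the alternatives; alternatives and tests added later are named as such. They were drawn from general knowledge of activity-regulated genes, cortical cell types and neighbouring tissues, which may include earlier publications on these samples. For the panel, p-values were also adjusted over the panel alone. For the lists, each gene was represented by its probe set with the highest mean. Lists with at least 5 measured genes (16 of them) were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and, as an alternative, with the correlation estimated from the data. Fry, a rotation test of whether a list's genes moved one way on balance, was a further alternative. The genes named in the text are the probe sets of the panel, the 24 probe sets of 1 gene with the smallest p (since fewer than 20 passed the adjusted threshold, where the 12 largest changes each way would have been named), and from each list the 2 to 4 members with the smallest p, with the 2 brightest members of lists of other cell types or tissues. Ier2, Klf4, Jun, Jund, Zfp36l2 and the bright members named from neuronal, layer and heat shock lists fall outside this rule and were chosen after their values were seen. Array-level measures were compared with exact two-sided permutation tests over the 252 assignments of 5 against 5 arrays; the pyruvate carboxylase ratio and the BioB and CreX spike-ins were added to the planned measures after the data were seen.

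Limma and camera were tested on simulated data with the means and spreads of the real arrays (7453 probe sets, 10 runs). Each run held 200 changed probe sets, 50 at each of 4 fold changes from 1.5 to 4. At an adjusted p of 0.05, 67.2% of probe sets changed 1.5-fold and 97% of those changed 2-fold were recovered, and 4.94% of calls were false. A larger number of true changes eases the Benjamini-Hochberg adjustment, so these rates do not carry over to data with few changes. A list given a log2 shift of -0.3 was called in 20 of 20 runs; the simulated genes were independent of one another, unlike real ones. The alternatives were quantile normalization, median scaling, pseudocounts of 1 and 49, no filter and a filter at the 60th percentile, other variance models, the replicate number as a block, the mean of all probe sets of a gene for the lists, and leaving out each array in turn. Camera with an estimated correlation under each of these settings was added after the results were seen.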

Results

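Gene expression was compared between the 2 hemispheres of the visual cortex in young mice after removal of one eye at postnatal day 14. Most axons of the mouse optic nerve cross the midline, so the cortex contralateral to the removed eye loses most of its visual input. The ipsilateral cortex keeps the crossed input of the remaining eye. Tissue was taken at postnatal day 18, 4 days after surgery, and 5 deprived and 5 non-deprived samples were hybridised to 1 array each. Median signals of the arrays lay between 191 and 209 arbitrary units. Arrays of 1 group correlated with each other at 0.957 to 0.979 (Pearson, across the 7453 tested probe sets, which are not independent). The question of the design is which transcripts differ between cortex that lost its main eye input and cortex that kept it. All 10 samples came from mice after removal of one eye, so there is no intact control. A gene that fell or rose is one lower or higher in deprived than in non-deprived cortex.

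The 7 probe sets with the smallest p in the comparison all belonged to genes that neuronal activity regulates, and all 7 were lower in deprived cortex. Of the 15 genes of the preset panel, 12 had at least 1 tested probe set. Adjusted over the panel alone, 9 of these genes fell and none rose. Adjusted over all 7453 tested probe sets, none passed 0.05, and the smallest adjusted p in limma was 0.0503. The panel may draw on earlier publications on these samples, so the adjustment over the panel alone may not be independent of them. Junb, an AP-1 transcription factor, had a signal of 552 ± 121 in deprived cortex against 1115 ± 184 in non-deprived cortex (SD, n = 5 each). On this probe set, an incomplete one, it fell by 1.00 ± 0.15 (SE) on the log2 scale, or 50.1%. Fos, the partner of Jun proteins in AP-1, fell from 3792 ± 629 to 2069 ± 424 (SD, n = 5 each; log2 -0.88 ± 0.15 SE). Nr4a1, an orphan nuclear receptor, fell from 3613 ± 811 to 1989 ± 446 (log2 -0.85 ± 0.18 SE). The zinc-finger factors Egr2 and Egr1 had log2 differences of -0.71 ± 0.16 and -0.47 ± 0.10 (SE), and Fosb one of -0.39 ± 0.12.

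Of the panel genes that are not transcription factors, both measured phosphatases and the neurotrophin fell as well. Dusp6, a phosphatase that inactivates ERK, went from 2758 ± 350 to 1783 ± 121 (SD, n = 5 each), which is 34.8% lower (log2 -0.62 ± 0.09 SE). Dusp1, which acts on several MAP kinases, was 32.6% lower (log2 -0.57 ± 0.13 SE). Bdnf, brain-derived neurotrophic factor, was 32% lower, at 1388 ± 234 against 2033 ± 208 (SD, n = 5 each; log2 -0.56 ± 0.12 SE). All 5 deprived arrays lay below all 5 non-deprived arrays for Junb, Dusp6, Fos, Egr1, Bdnf and Egr2. Nptx2, a secreted pentraxin of excitatory synapses, had a log2 difference of -0.28 ± 0.13 (SE) that did not pass over the panel (adjusted p = 0.0592). It did pass without deprived replicate 5, without non-deprived replicate 2, under median scaling, with a filter at the 60th percentile and with the replicate number as a block. Nr4a2, the closest relative of Nr4a1 on the panel, had a log2 difference of -0.02 with a 95% interval from -0.34 to 0.29. The synaptic scaffold gene Homer1 had one of 0.02 with an interval from -0.44 to 0.49 and signals of only 141 and 136. The estimate for Homer1 turned negative under quantile normalization and median scaling. Arc, Egr4 and Dusp14 were not analysed here.

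**Figure D1:**
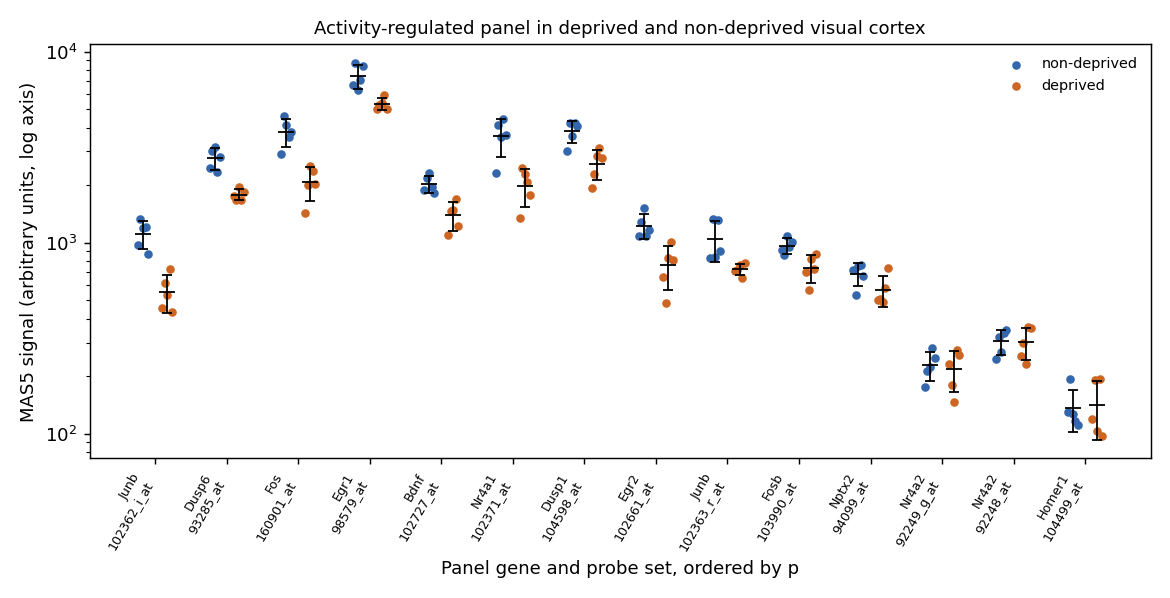
MAS5 signal (arbitrary units, log axis) of the 14 tested panel probe sets, ordered by p, in non-deprived (blue) and deprived (orange) cortex. Each dot is an array and the bars give the mean ± SD (n = 5 per group); the 10 probe sets on the left, from Junb to Fosb, passed the threshold adjusted over the panel alone, and Nptx2, Nr4a2 and Homer1 did not.

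The 10 panel probe sets that passed had limma adjusted p-values from 9.44e-05 (Junb and Dusp6) to 0.00663 (Fosb) over the panel alone. The second probe set of Junb, of relaxed design rules, gave a smaller log2 difference of -0.48 ± 0.14 (SE). Dim second probe sets of Fos, Egr1, Dusp6 and Homer1 lay below the signal filter and were not tested. Those of Fos and Egr1 had means of 97.1 and 123 in deprived against 86.5 and 104 in non-deprived cortex, the other way round. Over all 7453 probe sets no single gene passed an adjusted p of 0.05 in limma: the smallest value was 0.0503, shared by Junb and Dusp6, followed by Fos at 0.105. At an unadjusted p under 0.05 there were 357 probe sets, 181 higher and 176 lower, against 373 that chance would give. At an unadjusted p under 0.001 there were 14, of which 11 were lower in deprived cortex, against 7.45 by chance. The count at an adjusted p of 0.05 was 5 without non-deprived replicate 1 (Btg2, Fos, Dusp6, Junb and Nr4a1, all lower), and 1 without deprived replicate 4 (Junb). It was 0 without any other single array. It was 2 (Junb and Dusp6, both lower) with a pseudocount of 49 or a filter at the 60th percentile, and 1 (Dusp6) with the actin 3' over 5' ratio as a covariate, which was added after the results were seen. With the replicate number as a block it was 6, all lower (Junb, Nr4a1, Fos, Dusp6, Capn1 and Dusp1). The labels do not say whether same-numbered samples share animals, so the block is given as an alternative only.

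Among the 24 genes with the smallest p, 18 had lower and 6 had higher means in deprived cortex, and none passed over all probe sets. Besides 8 panel genes (Junb, Dusp6, Fos, Egr1, Bdnf, Nr4a1, Dusp1 and Egr2), the lower ones included Btg2, Gadd45g, Gadd45b, Ddit3, Sertad1 and Ifrd1. Btg2, an antiproliferative early-response gene, had a log2 difference of -0.64 ± 0.13 (SE), the growth-arrest gene Gadd45g one of -0.39 ± 0.10. Its relative Gadd45b had one of -0.60 ± 0.15 on a family-type probe set, while a second Gadd45b probe set gave -0.24 ± 0.15. The stress-linked transcription factor Ddit3 had a log2 difference of -0.53 ± 0.14 (SE), Sertad1 one of -0.63 ± 0.15, and Ifrd1 one of -0.57 ± 0.14. The remaining lower genes were Capn1, a calcium-dependent protease with signals of 217 ± 89.1 against 433 ± 99.5 (SD, n = 5 each), Zfp106 (log2 -0.59 ± 0.14 SE), Mest (-0.55 ± 0.15) and Pon2 (-0.41 ± 0.10). A second tested probe set of Zfp106 gave -0.12 ± 0.14.

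The 6 genes with higher means had all 5 deprived arrays above all 5 non-deprived arrays. Eef1b2, a translation elongation factor subunit, had signals of 209 ± 83.4 against 80.1 ± 17.2 (SD, n = 5 each; log2 1.16 ± 0.26 SE). Med27, a Mediator subunit, had 1698 ± 350 against 1115 ± 127 (SD, n = 5 each; log2 0.59 ± 0.13 SE). Both were read by probe sets of relaxed design rules. Sfxn1, a mitochondrial serine carrier, had a log2 difference of 0.53 ± 0.12 (SE), and Nfkbia, an inhibitor of NF-kappaB, one of 0.40 ± 0.11. The ribosomal protein gene Rps29 had one of 0.39 ± 0.10 and Tmeff2 one of 0.37 ± 0.10. The other tested probe set of Nfkbia gave -0.03 ± 0.13, and second probe sets of Eef1b2 and Rps29 were not among those tested. Over all 7453 probe sets, the 2 groups did not overlap for 71, or 0.953%, against the 0.794% that chance gives for 5 against 5.

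Taken as lists, the preset effector genes of activity were lower in deprived cortex relative to all other genes. The preset immediate early transcription factors were lower as well, but with an estimated correlation between genes this call was lost in 13 of 22 settings, among them 9 of 10 single-array omissions. Of 23 measured immediate early transcription factors, 7 fell, adjusted over the list alone (Fos, Btg2, Egr1, Nr4a1, Egr2, Junb and Fosb), none rose and 16 did not pass. The list mean was -0.29 on the log2 scale and the median -0.19. Among the 16, Ier2 had a log2 difference of -0.48 ± 0.18 (SE) and Klf4 one of -0.44 ± 0.18, whereas Jun had one of 0.0045 ± 0.15. Of 22 measured effector genes of activity, 2 fell (Bdnf and Gadd45g) and none rose. The 20 others included the cell-cycle inhibitor Cdkn1a (log2 -0.37 ± 0.12 SE) and the activin subunit gene Inhba (-0.40 ± 0.14). Of the 22 estimates, 19 were below 0, with a list mean of -0.18.

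Camera gave the immediate early list an adjusted p of 7.1e-11 at the preset correlation, and an adjusted p = 0.0393 with an estimated correlation. For the effector list these were 1.4e-08 and an adjusted p = 0.00263 with an estimated correlation. Both calls thus held with all 10 arrays and the planned settings. With single arrays left out, the immediate early list kept its call in 1 of 10 cases (without non-deprived replicate 1) and lost it in 9, at an adjusted p = 0.0545 to 0.104 with an estimated correlation. It also lost it under quantile normalization (adjusted p = 0.0515 with an estimated correlation) and median scaling (adjusted p = 0.108 with an estimated correlation). The effector list kept its call in all 10 single-array omissions, at an adjusted p = 0.00482 to 0.00911 with an estimated correlation. These combinations were added after the results were seen. At the preset correlation, 57 of 99 other divisions of the arrays into 5 and 5 also called at least 1 list. Fry gave adjusted p-values of 0.0407 and 6.33e-05. Without the panel genes, an alternative added after the results were seen, the 16 remaining immediate early genes had a mean of -0.17 and an adjusted p of 0.00229, but an adjusted p = 0.252 with an estimated correlation. The 19 remaining effector genes kept a mean of -0.17, with an adjusted p = 0.00629 with an estimated correlation.

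The MAP kinase pathway list did not pass as a whole. Of its 21 measured genes, Dusp6 and Dusp1 fell, adjusted over the list alone, and the kinases and adaptors lay on both sides of 0. Of all estimates, 10 were above and 11 below, with a median of -0.0045, a mean of -0.05 and a camera adjusted p of 0.241 (with a filter at the 60th percentile, 0.0497 at the preset correlation but an adjusted p = 0.411 with an estimated correlation). Spred2, an inhibitor of Ras-ERK signalling, had a log2 difference of -0.25 ± 0.10 (SE) and Spry4, another such inhibitor, one of 0.37 ± 0.16, neither of which passed. Without the panel genes, the list mean was 0.0059.

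**Figure D2:**
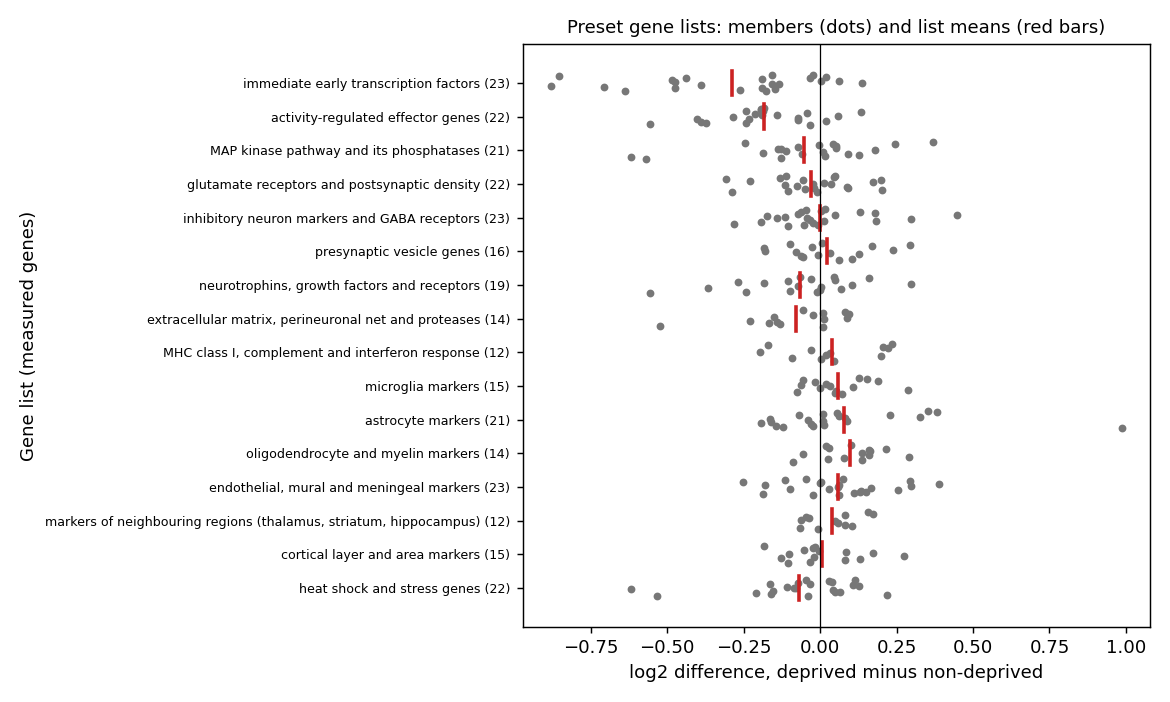
Log2 difference (deprived minus non-deprived) of every measured gene (dots) in the 16 tested gene lists, with the mean of each list as a red bar and the number of measured genes in brackets. The means of the immediate early list (-0.29) and the effector list (-0.18) lie farthest from 0.

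No list of synaptic genes passed the test, and no member of them passed, adjusted over the list alone. The 22 measured glutamate receptor and postsynaptic genes had a mean log2 difference of -0.03 (camera adjusted p = 0.499) and the 16 presynaptic genes one of 0.02 (adjusted p = 0.965). The 23 inhibitory neuron and GABA receptor genes had one of -0.00094 (adjusted p = 0.927). Among bright neuronal transcripts, Snap25, a vesicle fusion protein, had mean signals of 13053 and 12765 in deprived and non-deprived cortex. Gad1, which makes GABA, had 4653 and 4760, and the AMPA receptor subunit Gria2 8162 and 8571. The members with the smallest p were Cnih2 and Grin2c in the postsynaptic list (log2 0.20 ± 0.09 and -0.23 ± 0.11 SE). They were Syt2 and Syn2 in the presynaptic list (0.29 ± 0.10 and -0.18 ± 0.09), and Kcnc1 and Pvalb among inhibitory markers (0.45 ± 0.17 and 0.18 ± 0.08). The 15 cortical layer and area markers had a mean of 0.01 and a median of -0.02 (adjusted p = 0.984), led by Epha7 (0.27 ± 0.11) and Cux1 (-0.13 ± 0.08). Tbr1, a marker of deep-layer neurons, had mean signals of 6307 and 6334. The growth factor list (19 genes, mean -0.07, adjusted p = 0.273) held Bdnf as its 1 member that fell, followed by Igf2 (0.30 ± 0.13). The 14 matrix and protease genes had a mean of -0.08 (adjusted p = 0.288), with Sparc at -0.15 ± 0.09 and Chst3 at -0.52 ± 0.36.

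No list of markers of other cell types or of neighbouring tissue passed, and none of their members did, adjusted over the list alone. The 14 oligodendrocyte and myelin genes had a mean log2 difference of 0.10 (camera adjusted p = 0.167; adjusted p = 0.621 with an estimated correlation), with Mag at 0.29 ± 0.15 (SE), Pdgfra at 0.22 ± 0.14, Mobp at 0.14 ± 0.11 and Mbp at -0.06 ± 0.11. At the preset correlation the list passed without deprived replicate 3 (adjusted p of 0.00239) and without non-deprived replicate 4 (0.00719), but not with an estimated one (adjusted p = 0.468 and 0.473 with an estimated correlation). The 21 astrocyte genes had a mean of 0.08 (adjusted p = 0.439), led by Agt, angiotensinogen, at 188 against 91.4 (log2 0.99 ± 0.35 SE), and Slc4a4 (0.35 ± 0.13). The bright markers Cpe and Mt3 had -0.03 ± 0.08 and 0.23 ± 0.19. The 15 microglial genes had a mean of 0.06 (adjusted p = 0.273), with Cd53 at 0.29 ± 0.15, Laptm5 at 0.19 ± 0.11, and the bright Apoe and Ctsb at 0.05 ± 0.08 and 0.03 ± 0.07. The 12 genes of MHC class I, complement and the interferon response had a mean of 0.04 (adjusted p = 0.499), with Tapbp at 0.24 ± 0.14, C1qc at 0.20 ± 0.12 and the bright C1qa at 0.0022 ± 0.11. The 23 vascular and meningeal genes had a mean of 0.06 (adjusted p = 0.288), with Cldn5, a tight-junction gene of endothelium, at -0.19 ± 0.09, Igf2 at 0.30 ± 0.13 and Ptgds at 0.39 ± 0.25. The 12 markers of thalamus, striatum or hippocampus had a mean of 0.04 (adjusted p = 0.499), with Zic1 at 0.16 ± 0.14, Pde1b at 0.08 ± 0.08 and Penk at 0.06 ± 0.12. The choroid plexus and erythrocyte lists had 4 and 3 measured genes, too few for the list test. Igf2 had signals of 2588 and 2063, Igfbp2 643 and 732, and the globins Hba-a1 4169 and 3462 and Hbb-b2 948 and 913. Alas2, a heme synthesis gene of erythrocytes, had 236 and 219 (log2 0.09 ± 0.18 SE).

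The heat shock and stress list (22 genes) had a mean of -0.07 and a camera adjusted p of 0.241. Ddit3 fell, adjusted over the list alone (adjusted p = 0.0473), and no other member passed. Hspa1a, an inducible heat shock protein, had a log2 difference of -0.62 ± 0.26 (SE) and Ddit4, an inhibitor of mTOR signalling, one of 0.22 ± 0.08. The bright chaperone genes Hsp90aa1 and Hspa8 had differences of -0.15 ± 0.14 and -0.11 ± 0.07.

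No measure of array quality passed a test between the groups. The ratio of 3' to 5' signal of the beta-actin control probe sets, which rises with RNA degradation, was 1.58 ± 0.121 in deprived and 1.58 ± 0.181 in non-deprived arrays (SD, n = 5 each; exact two-sided permutation p = 0.96). That of Gapdh was 1.04 ± 0.0729 and 1.00 ± 0.0748 (SD, n = 5 each; exact permutation p = 0.405). The share of probe sets with a signal under 16 was 9.69% ± 1.98 and 10.7% ± 0.558 (exact p = 0.381). The median signal was 201 ± 7.26 and 196 ± 3.81 (exact p = 0.254). Of 7 such measures, with the pyruvate carboxylase ratio and the BioB and CreX spike-ins as the others, none had a Benjamini-Hochberg adjusted exact p below 0.917. The smallest p this design allows is 0.00794. The labels give no scan date or batch.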

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

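The tests of neuron share, of RNA degradation, of the arrays numbered 1, and of splits for single lists and for the list count with an estimated correlation, were chosen after the results were seen. The splits for the panel, for the probe set count at an adjusted p of 0.05 and for the list count at the preset correlation were planned. The lower panel in deprived cortex was weighed against 3 explanations. Of 100 splits of the 10 arrays into 5 and 5 (of 126 possible), only the real 1 gave 10 panel probe sets past the threshold. A chance division of the arrays is thus an unlikely source of that count. The highest other split gave 8 and exchanged deprived replicate 4 with non-deprived replicate 1. The splits exchange arrays, not animals, and cannot weigh a panel that may draw on earlier publications on these samples, so chance is not excluded. A lower share of neurons in the deprived samples would lower neuronal transcripts in step, but the mean of 38 presynaptic and glutamate receptor genes differed by -0.0073 on the log2 scale (95% interval -0.13 to 0.12), against -0.49 for the 14 panel probe sets. The values argue against RNA degradation, as read from the actin 3' over 5' ratio, as the whole cause. The group means of the ratio were 1.58 and 1.58, and its log2 value differed by -0.0028 (95% interval -0.20 to 0.19). With the log2 ratio as a covariate the mean of the 14 panel probe sets differed by -0.49 (95% interval -0.71 to -0.28). That fit adds little, since a ratio so alike between the groups could take up almost none of the difference. With the covariate, 402 probe sets in place of 357 had an unadjusted p under 0.05. The log2 Gapdh and pyruvate carboxylase ratios were higher in deprived arrays, by 0.058 (95% interval -0.09 to 0.21) and 0.147 (-0.32 to 0.61), both intervals including 0. With these ratios as the covariate in turn, the mean of the 14 panel probe sets differed by -0.505 (95% interval -0.73 to -0.28) and -0.495 (-0.72 to -0.27). Loss of eye input is the candidate explanation that the design names, untested here beyond the group difference itself; whether handling, or removal of the eye rather than loss of vision, contributed was not tested.

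All 100 splits gave at least the 0 probe sets of the real split at an adjusted p of 0.05 (highest other, 1), and 41 gave at least its 357 at an unadjusted p under 0.05, the highest 861. At the preset correlation, 34 of 100 splits called at least 2 lists, as the real one did, the highest other called 4, and 57 of the 99 other splits called at least 1, so chance cannot be excluded for that count and camera's preset p-values are too small here. With an estimated correlation, 1 of 100 splits, the real one, called 2 lists, and the highest other called 1. This test was chosen after the results were seen and rests on 2 lists against 1, so it does not exclude chance. With single arrays left out, the count of lists called was 1 in 9 of 10 cases. The list means were as far from 0 in 1 of 100 splits each, the real one: 0.286 in size against 0.280 for the highest other for the immediate early list, with non-deprived replicate 1 again among the arrays moved, and 0.183 against 0.132 for the effector list.

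Both arrays numbered 1 had the lowest mean of the 10 panel probe sets in their group, 10.2 on the log2 scale in deprived and 10.9 in non-deprived cortex. The 5 same-number differences ran from -0.89 to -0.52. A candidate explanation is that same-numbered arrays share animals or a processing day. The SD of these differences was 0.14, against a median of 0.23 over all 120 pairings of the arrays. Of the 120 pairings, 16 gave an SD as small, so this score alone cannot tell the numbering from a chance pairing. Deviations from the group means over many probe sets say more. Same-numbered arrays correlated in them at 0.14, 0.18, 0.22 and 0.23 for numbers 1 to 4. The highest correlations with another number were 0.02, 0.01, 0.09 and 0.01. For deprived replicate 5 the correlation was 0.02, against 0.03 with another number, while non-deprived replicate 5 correlated best with its own number. The values thus go with a link between same-numbered arrays for numbers 1 to 4, and are mixed for number 5. Whether animals or a processing day were shared was not tested.

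In 74 groups of 5 values, 4 held an array far from the other 4, where chance gives about 1 in 20. Tmeff2 had a signal of 387.9 in non-deprived replicate 3, against 476 to 497 in the others. Homer1 had 193.7 in non-deprived replicate 2, against 111 to 130. The beta-actin 3' over 5' ratio was 1.90 in non-deprived replicate 3, against 1.45 to 1.56, and the pyruvate carboxylase ratio was 5.35 in deprived replicate 2, against 2.72 to 3.29.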

How the results depend on the processing

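The alternatives with the panel genes left out of the lists, with the actin ratio as a covariate, and with an estimated correlation under each other setting were chosen after the data were seen. The same 10 panel probe sets passed, adjusted over the panel alone, under each of the 20 alternatives and single-array omissions run on them, with 10 or 11 calls in all. The additional probe set was Nptx2. The immediate early list kept a negative mean in all alternatives (-0.38 to -0.17). Its call depended on whether camera was run with a preset or an estimated correlation. The call held in all 22 settings at the preset value, but in 9 of 22 with an estimated one (adjusted p = 0.00651 to 0.252 with an estimated correlation). It was lost without the panel genes (mean -0.17, adjusted p = 0.252), with the replicate block (-0.286, 0.0675), under quantile normalization (-0.296, 0.0515) and median scaling (-0.32, 0.108), and in 9 of 10 single-array omissions, whose means ran from -0.34 to -0.24. There 1 list in place of 2 passed, with 1 to 3 lists over all omissions at either correlation; the cause was not tested. The effector list passed in all 22 settings at either correlation (mean -0.24 to -0.17, adjusted p = 0.000834 to 0.0472 with an estimated correlation). The count of probe sets at an adjusted p of 0.05 was 0 in the main setting, 2 (both lower, Junb and Dusp6) with a pseudocount of 49 or a filter at the 60th percentile, 1 (lower) with the actin covariate, and 0 to 5, all lower, when single arrays were left out; the cause was not tested. With the replicate block the count was 6, all lower (Junb, Nr4a1, Fos, Dusp6, Capn1 and Dusp1). Same-numbered arrays correlated in their deviations from the group means at 0.14, 0.18, 0.22, 0.23 and 0.02 for numbers 1 to 5. Each of the 10 arrays except deprived replicate 5 correlated best with its own number, a hint of pairing that falls short of the criterion of 0.1 in every pair. In the replicate block fit the oligodendrocyte list passed (mean 0.10, adjusted p = 0.0401) at the preset correlation only (adjusted p = 0.25 with an estimated correlation). Its mean ran from 0.034 to 0.159 when single arrays were left out, and its adjusted p from 0.00239 to 0.880 over all alternatives. The count at an unadjusted p under 0.05 was 625 with no filter and 223 at the 60th percentile, as more or fewer probe sets were tested. The MAP kinase list passed at the 60th percentile at the preset correlation only (mean -0.095, adjusted p = 0.0497, against an adjusted p = 0.411 with an estimated correlation and a range up to 0.958 over the alternatives), and its mean was 0.0059 without the panel genes, at either correlation.

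The following values changed sign without passing a threshold, and the cause was not tested. Homer1 went to -0.035 under quantile normalization and -0.0092 under median scaling. The presynaptic list mean went to -0.013 and the cortical layer list mean to -0.029 under median scaling; the latter was -0.00076 with no filter and -0.0076 with all probe sets of a gene averaged. The inhibitory list mean was 0.00049 with a pseudocount of 1, and the MHC and interferon list mean -0.030 with no filter. When single arrays were left out, the means ran from -0.016 to 0.026 for the cortical layer list, from -0.057 to 0.010 for glutamate receptors, from -0.027 to 0.018 for inhibitory markers, from -0.011 to 0.068 for MHC and interferon genes and from -0.0055 to 0.069 for presynaptic genes. Homer1 ran from -0.096 to 0.14, and the 2 probe sets of Nr4a2 from -0.094 to 0.061 and from -0.17 to 0.044. Group differences of the array measures ran from -0.040 to 0.072 for the actin ratio, from -0.064 to 0.59 for the pyruvate carboxylase ratio, from -39.1 to 69.7 for BioB and from -882 to 1460 for CreX. The share of signals under 16 differed by -1.52 to -0.16 percentage points, with an exact permutation p of 0.0397 without deprived replicate 4. Without an intensity trend in the variance, the smallest adjusted p over all probe sets rose to 0.214. The simulated recovery of 67.2% of 1.5-fold changes came with 200 changed probe sets per run and does not carry over to data with few changes. In the real data Junb, 2.01-fold lower, and Dusp6, 1.53-fold lower, both had an adjusted p of 0.0503 in limma. The share of single-gene changes missed with 5 arrays per group is therefore not known.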

Other observations

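All tests in this part except that of genes following the panel were chosen after the results were seen. Astrocyte genes held 3 members with higher means at an unadjusted p under 0.05, which do not pass over their list (adjusted p = 0.116 each): Agt, the bicarbonate transporter gene Slc4a4 and the glutamate transporter gene Slc1a2, with log2 differences of 0.99 ± 0.35, 0.35 ± 0.13 and 0.38 ± 0.14 (SE). The mRNA decay factor gene Zfp36l2, singled out after its values were seen, had -0.39 ± 0.12 (SE) on 1 probe set and -0.04 ± 0.20 on another.

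Within transcription factor families, members were compared with each other inside each array. Of the Nr4a receptors, Nr4a1 had a log2 difference of -0.85 and Nr4a2 one of -0.02, and within arrays Nr4a1 moved by -0.83 relative to Nr4a2 (95% interval -1.33 to -0.33; exact permutation p = 0.0159, 0.0317 adjusted over 4 family pairs). Junb moved by -1.01 relative to Jun (interval -1.62 to -0.39; exact adjusted p = 0.0317), and by -0.49 on its second probe set (interval -1.04 to 0.065, which includes 0; exact p = 0.0397), while Jund, another member, had a log2 difference of -0.00041 ± 0.12 (SE). Fos moved by -0.49 relative to Fosb (interval -0.94 to -0.04; exact adjusted p = 0.0317). For Egr2 relative to Egr1 the difference was -0.23 (interval -0.72 to 0.25; exact adjusted p = 0.405), which leaves open whether they differ. The first 3 differences kept their sign and lay within 0.05 of these values under quantile normalization, median scaling and the other pseudocounts. In non-deprived cortex Nr4a2 and Jun were dimmer than their partners, at 304 against 3613 for Nr4a1 and 344 against 1115 for Junb. Whether signal level contributed to these differences was not tested. The 4 pairs were picked after their values were seen, so these p-values describe the pairs and do not test whether family members respond differently.

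Genes outside the lists that follow the panel within groups may share its control, so they were predicted to be lower in deprived cortex as well. The 50 of 7098 candidate probe sets that tracked the panel score most closely within groups had a median log2 difference of -0.032. Of 1000 seed sets of unrelated genes of like signal, 19.6% gave a median as low, and the middle 95% ran from -0.074 to 0.088. The prediction was not met: 1 of the 50 was lower and 2 were higher at an unadjusted p under 0.05. The lowest within-group correlation among the 50 was 0.75. Whether the closest of 7098 probe sets would reach such values by chance over so few arrays was not tested. The 50 are therefore not shown to follow the panel, and the result does not decide whether genes that share its control were lower.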
